A study of Mus musculus with 42 samples.

How the data were processed

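The study measured polyadenylated RNA by sequencing in 42 libraries from 7 mouse cancer cell lines. B16 is a melanoma line, CT26 and MC38 are colon carcinoma lines, EG7 is a lymphoma line that carries an ovalbumin gene, LLC is a lung carcinoma line, Pan02 is a pancreatic carcinoma line and WEHI3 is a myelomonocytic leukaemia line. Cells of each line were kept for 6 h in 10 µM RECTAS with 0.1% DMSO, or in 0.1% DMSO alone. RECTAS is a small molecule known as a splicing modulator that acts through CLK kinases and the SR protein SRSF6. Each of the 14 groups of line and treatment held 3 libraries. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples.

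Per the labels, libraries were made with the TruSeq stranded mRNA kit, and the submitters' processing notes name HISAT2 2.2.0, RSEM 1.3.0 and the GRCm38 genome without saying what each was used for. The strand setting, the annotation release and any filter are not given in the sources used here. The deposited values were TPM per gene, a share of all transcripts of a library corrected for gene length, 1 file per library with 55401 genes in each. The values summed to between 999998 and 1000003 in every library, the smallest value above 0 was 0.01, and no scaling between libraries was seen. TPM values carry no read counts, so the depth of each library is unknown and no counting interval could be given. In their place, the agreement of replicates was measured: the correlation of log2(TPM + 1) between replicates of a group was 0.984 to 0.991 across genes, and the SD of their log2 difference was 0.281 to 0.377.

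Gene IDs were looked up in the GENCODE M21 mouse annotation on GRCm38, where 55141 IDs (99.5%) matched. The 107 symbols shared by several IDs were kept as separate genes. Genes that overlap another gene, on the same or the opposite strand, and genes with near-identical copies are uncertain, because reads can be assigned to either partner. Beside those described so in the results, this holds for genes taken by the naming rule that overlap another: Xkr5 (Gm22551), Evi5 (Gm43592), Nacc2 (Gm13554), Tmem250-ps (1810012K08Rik), Pak1ip1 (A730081D07Rik), Pop4 (Gm44767), Rsph3a (E430024P14Rik), Rsph3b (Gm49719), Clk3 (Edc3) and Clk4 (Gm25082).

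Differences between RECTAS and DMSO were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with moderated variances, an intensity trend and two-sided tests. Each line was fitted alone on its 6 libraries, over genes with a mean of at least 1 TPM in that line. A fit of all 42 libraries with 14 group means, over the genes that reached a mean of 1 TPM in every line, gave the mean of the 7 within-line differences and an F-test, with 6 degrees of freedom, that the 7 differences were equal. Benjamini-Hochberg adjusted p-values under 0.05 were called. Genes called in the same direction in at least 3 lines were counted beside the number expected if the 7 sets of calls were independent. The likeness of the lines was measured as the mean Pearson correlation of the gene differences over the 21 pairs of lines, with a one-sided permutation test of 100000 draws that relabelled the libraries within each line. On the log2(TPM + 1) scale the difference understates the fold of genes with low TPM.

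Gene lists were tested with camera at a preset correlation of 0.01, where at least 5 members were tested, with Benjamini-Hochberg adjustment over the lists. The 28 lists were SR proteins; CLK, SRPK and DYRK kinases; hnRNP proteins, core spliceosome, nonsense-mediated decay factors, p53 targets, the ATF4 integrated stress response, the endoplasmic reticulum unfolded protein response, the heat shock response, NRF2 targets, aryl hydrocarbon receptor targets, MHC class I antigen presentation, interferon-stimulated genes, NF-kB targets, cholesterol synthesis and uptake, immediate early genes, G1/S genes, G2/M genes, hypoxia and glycolysis, ribosome biogenesis, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, nuclear-encoded oxidative phosphorylation, and markers of melanocytes, T lymphoid, myelomonocytic, epithelial and mesenchymal cells. A score per library, the mean log2(TPM + 1) of a list's members, was tested for equal differences between the lines with the limma F-test. The share of mitochondrially encoded transcripts was compared with an exact two-sided permutation test, which cannot go below 0.1 for 3 libraries against 3.

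The tests, lists, thresholds and the rule for naming genes were chosen before the data were examined. The rule took, on average over the lines, the 12 largest rises and 12 largest falls among called genes with the same sign in all 7 lines. In each line it took the 4 largest rises and falls among called genes whose RECTAS libraries all lay above, or all below, the DMSO libraries. Between lines it took the 10 genes with the smallest adjusted p of the F-test, and in each list the 4 members with the smallest p. Clk1, Clk2, Clk3, Clk4 and Srsf6 were always named, some genes are not reported here, and provisional gene symbols, clone names and mitochondrial genes were passed over outside the lists.

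The alternatives were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-ratio scaling, quantile normalization, TPM recalculated without mitochondrial genes, no intensity trend, a robust fit, replicate number as a block, a minimum log2 difference of 0.58, a spread shared by all 42 libraries, an additive fit of cell line and treatment, the 7 lines as units, camera with an estimated correlation, the fry rotation test, Spearman correlation, and leaving out each library or line in turn. A covariate for the main axis of variation between replicates and the removal of a trend in GC content and gene length were added after the data were seen.

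The fits were tested on simulated data with 200 changed genes. In single lines, 31.2% to 59.0% of genes changed by 0.3 on the log2 scale were recovered, 64.6% to 86.6% of genes changed by 0.58 and 84.2% to 98.2% of genes changed by 1, and 1.64% to 8.18% of the calls were false. On average over the lines, 98.4% were recovered at 0.3, and 8.96% of the calls were false. Among the lists, 1 was called in the simulation without a shift. The simulated noise was independent between genes, while in the real libraries the main axis held 14.5% of the variance within groups. The simulated shares of false calls may therefore not hold for the real libraries. No change under 0.3 was simulated, while the genes called on average in the real data had a median absolute difference of 0.0973. The shares recovered and false are not known for changes of that size. Figures were drawn with matplotlib 3.10.9, with tables handled in Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Splicing itself was not measured, because the files give 1 value per gene and none per transcript or junction.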

Results

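RNA was profiled in 7 mouse cancer cell lines after 6 h in 10 µM RECTAS or in its 0.1% DMSO vehicle, with 3 libraries for each line and treatment and 42 in all. The values were TPM per gene. Between 11001 and 12205 genes reached 1 TPM in a library, and the 10 most abundant genes took 8.64% to 12.04% of the total. The series describes a search for peptides that arise from splicing changes in RECTAS-treated tumour cells, and the comparisons below ask which genes differed in abundance between RECTAS and DMSO, in each line, on average over the lines and between the lines.

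Markers of the known origin stood out in some lines and were missing in others. The 8 melanocyte markers averaged 1321 ± 16.3 TPM (SD, n = 3) in B16 with DMSO, led by the pigment enzymes Tyrp1 at 7101 TPM and Dct at 1980 TPM, and at most 4.02 ± 0.122 TPM in another line. T lymphoid markers averaged 187 ± 2.18 TPM in EG7, with 9 of 10 at 1 TPM or more, and 229 ± 5.49 TPM in WEHI3, where 5 of 10 reached 1 TPM and Thy1 alone stood at 2179 TPM. Myelomonocytic markers averaged 197 ± 1.09 TPM in WEHI3, including the granule proteases Ctsg at 965 TPM and Prtn3 at 401.5 TPM, and 68.0 ± 1.61 TPM in B16, where the lysosomal protein Cd68 stood at 808 TPM. Epithelial markers averaged 462 ± 10.3 TPM in Pan02 and 39.2 ± 2.61 TPM in LLC, where 2 of 9 reached 1 TPM. They averaged only 0.0648 ± 0.0286 TPM in CT26 and 0.0322 ± 0.00444 TPM in MC38, where 0 of 9 reached 1 TPM. Mesenchymal markers averaged 176 ± 2.08 TPM in CT26, with all 9 above 1 TPM, 68.5 ± 1.08 TPM in MC38 and 2.99 ± 0.101 TPM in EG7. They did not set the colon lines apart, with 109 ± 2.26 TPM in B16, 66.0 ± 4.30 in LLC, 65.9 ± 6.40 in Pan02 and 42.9 ± 1.79 in WEHI3.

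Among genes the naming rule allowed, the largest rise shared by the lines was in H2bc4, which encodes a core histone H2B. Its mean over the lines went from 22.3 TPM with DMSO to 51.0 TPM with RECTAS, a rise of 1.09 ± 0.036 (SE) on the log2 scale, higher in 7 of 7 lines (limma, 3 libraries per group, adjusted p = 2.00e-21). H2bc4 (ENSMUSG00000018102) lies on GRCm38 chromosome 13 from 23684199 to 23692908 on the plus strand. H2bc21, another histone H2B gene, with 1 exon on chromosome 3 from 96221119 to 96223738, rose by 0.54 ± 0.024, from 5.27 to 7.42 TPM. Luc7l (chromosome 17, 26252896 to 26285504), a factor associated with the U1 snRNP of the spliceosome, rose by 0.45 ± 0.015, from 64.4 to 87.8 TPM, with an adjusted p of 4.02e-21. Other rises included Tbc1d32 (0.52), a protein of cilia, Phf7 (0.47), Pcyox1l (0.43) and Srl (0.42). Several rises are uncertain because another gene overlaps them. Ccl25, a chemokine gene opposite Elavl1 on chromosome 8, rose by 0.74 ± 0.038, from 16.2 to 27.5 TPM. Nprl3, opposite Mpg on chromosome 11 and encoding a subunit of the GATOR1 complex that restrains mTORC1, rose by 0.55 ± 0.022, from 34.7 to 51.9 TPM. Sdhaf4, an assembly factor of succinate dehydrogenase, rose by 0.53 ± 0.025 with Gm26524 on the other strand, and the same holds for Sp3os (0.48), which is antisense to Sp3. A second gene ID of Zc3h11a, which shares its locus with the first and with Gm38394, rose by 0.51.

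**Figure D1:**
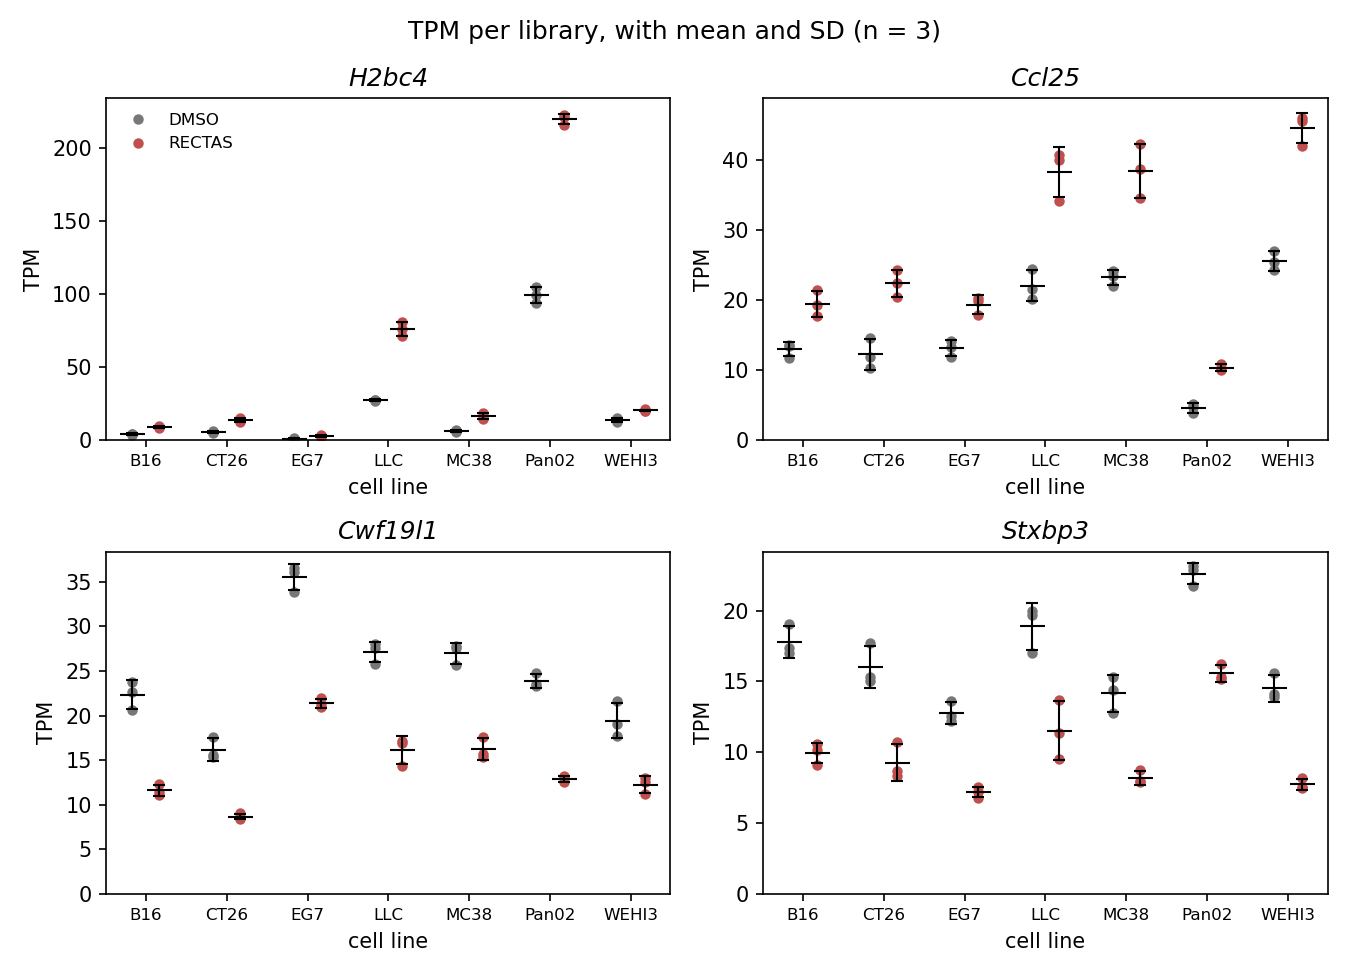
TPM of H2bc4, Ccl25, Cwf19l1 and Stxbp3 in each library of the 7 lines, with points for libraries and the mean and SD (n = 3) for DMSO and RECTAS. In LLC, for example, H2bc4 stood at 27.1 ± 0.555 TPM with DMSO and 76.0 ± 4.57 TPM with RECTAS, and each of the 4 genes moved the same way in all 7 lines.

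The largest shared fall that the naming rule allowed was in Cwf19l1 (chromosome 19, 44108637 to 44135876, 15 exons), which is related to a spliceosome-associated protein of yeast. It fell by 0.76 on the log2 scale (SE 0.026), from 24.5 to 14.1 TPM, and was lower in 7 of 7 lines with an adjusted p of 4.21e-21. Xkr5 (chromosome 8, 18932729 to 18950975, with Gm22551 on the other strand), a member of the XK-related family, fell by 0.75 (SE 0.021), from 11.4 to 6.58 TPM, with an adjusted p of 2.75e-23. Stxbp3 (chromosome 3, 108793176 to 108840526), which binds syntaxins in vesicle fusion, fell by 0.72 (SE 0.035), from 16.7 to 9.90 TPM. Alkbh3, a demethylase that repairs alkylated DNA and RNA, fell by 0.65 (SE 0.024), from 50.1 to 31.4 TPM, with Alkbh3os1 and Gm27027 overlapping it. The transporters Slc25a40 and Slc4a7 fell by 0.62 and 0.61, and Supt3, a subunit of the SAGA coactivator, fell by 0.58. The falls of Cwc27 (-0.68), a spliceosomal cyclophilin opposite Srek1ip1, of Ofd1 (-0.66), a centriolar protein opposite Trappc2, and of Cmc4 (-0.63), which overlaps Mtcp1, are uncertain. The radial spoke paralogs Rsph3b (-0.63) and Rsph3a (-0.61) are similar enough to share reads.

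Across all 8775 genes tested, 865 were called higher and 1396 lower on average over the lines, and the median absolute difference of the called genes was 0.0973 on the log2 scale. Only 3 rises and 12 falls reached a log2 difference of 0.58. Among the called genes, 375 rises and 753 falls had the same sign in all 7 lines. For these calls on average the balance of rises and falls depended on scaling. Falls were 61.7% of them as deposited, 51.0% after median-ratio scaling, 47.1% after quantile normalization and 45.6% with the GC and length trend removed. For genes called in the same direction in at least 3 lines, falls stayed in the majority. They were 75.0% as deposited, 69.1% after median-ratio scaling and 68.3% after quantile normalization. In single lines, falls were 53.7% (Pan02) to 69.6% (MC38) of the calls after median-ratio scaling.

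Single-line calls repeated across lines. At least 3 lines shared 32 rises and 96 falls, 128 genes where 0.858 would be expected by independence, and 14 rises and 39 falls were shared by at least 5 lines. Relabelling the libraries within lines gave up to 52 genes shared by at least 3 lines, so independence understates what other labellings can give. H2bc4, Sdhaf4 and Luc7l were called higher in all 7 lines, and Cwf19l1, Xkr5, Alkbh3, Supt3 and Ndufs3, a subunit of respiratory complex I, were called lower in all 7. Riox2 (-0.55), a histidine hydroxylase of the nucleolus, Atpsckmt (-0.46) and Dnajc8 (-0.41) were also called lower in all 7 lines and were chosen after their values were seen. Across genes, the log2 differences of pairs of lines had a mean Pearson correlation of 0.226 and a mean Spearman correlation of 0.294, and 20 of 21 pairs were above 0. The permutation p was 1e-05, the smallest the draws can give, and the highest of the relabelled means was 0.172. Genes are not independent replicates, so the p rests on relabelled libraries. The closest pair was CT26 and EG7 (0.389), while B16 and CT26 stood at -0.113. The count for at least 3 lines was 67 without the intensity trend, 39 with no filter and 22 with a log2 difference of at least 0.58.

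**Figure D2:**
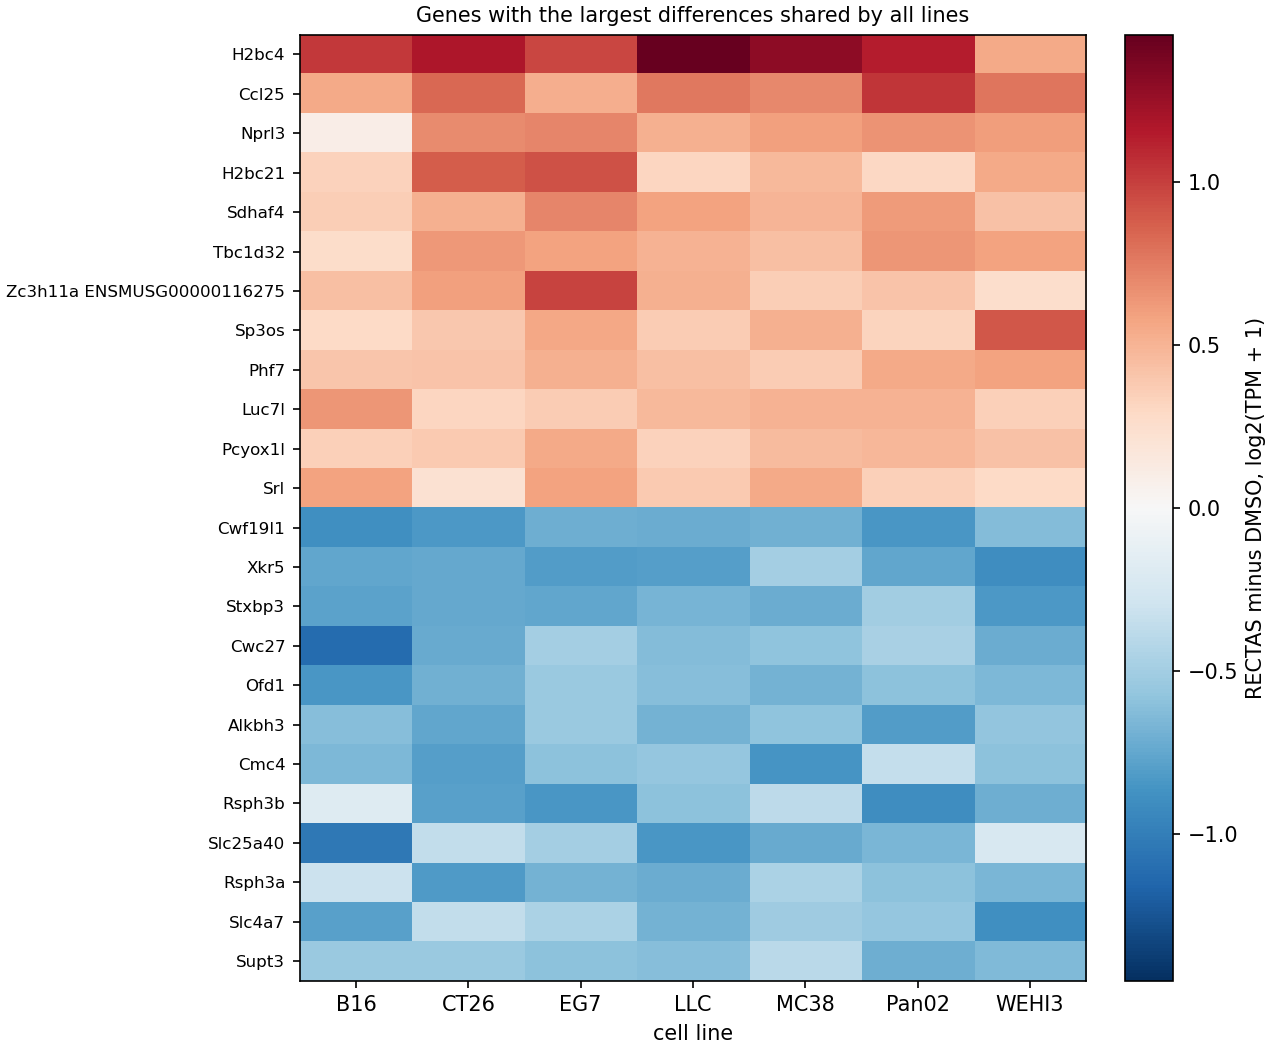
Log2 difference, RECTAS minus DMSO, in each of the 7 lines, on a colour scale from blue (lower) to red (higher). The genes are the 12 largest rises and 12 largest falls on average that the naming rule allowed. Each gene kept its sign in all 7 lines, and the sizes differed: Nprl3 rose by 0.71 in EG7 and stood at 0.10 in B16.

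RECTAS is known to act through CLK kinases and SRSF6, so these genes were read in every line. Srsf6 (chromosome 2, 162931528 to 162937121), an SR protein that promotes exon inclusion, rose by 0.15 ± 0.0094 on average, from 181.1 to 201.4 TPM, higher in 7 of 7 lines with an adjusted p of 1.01e-14. It was called in B16, CT26, MC38 and WEHI3, with the largest difference in WEHI3, from 123 ± 1.41 to 147 ± 4.48 TPM. With the main axis of variation between replicates as a covariate only the WEHI3 call held (adjusted p = 0.0131). The differences in B16 (0.19 before and after, SE 0.03 before and 0.06 after, adjusted p = 0.538), CT26 (0.19 and 0.18, SE 0.03 in both, 0.0513) and MC38 (0.16 and 0.15, SE 0.03 in both, 0.0763) changed little in size and no longer passed. The CLK kinases did not pass the test on average in the planned fit: the log2 differences were 0.01 for Clk1 (adjusted p = 0.931), -0.07 for Clk2 (0.0725), -0.06 for Clk3 (0.0805) and 0.05 for Clk4 (0.501). The call of Clk2 depended on the setting, with an adjusted p of 0.0252 with that covariate, 0.0475 without CT26 and 0.0491 without EG7, and up to 0.211 elsewhere (without WEHI3). It was 0.0258 to 0.0464 without RECTAS replicate 1 of B16, CT26 or EG7, LLC DMSO replicate 2, LLC RECTAS replicate 3, MC38 DMSO replicate 1 or Pan02 DMSO replicate 3. That of Clk3, which overlaps Edc3, was 0.0213 to 0.0490 without DMSO or RECTAS replicate 2 of B16 or RECTAS replicate 1 of LLC or MC38. The difference in Clk1 varied between lines (F-test adjusted p = 0.0290): in B16 it fell by 0.63, from 52.8 ± 4.06 to 34.0 ± 5.83 TPM, while the values were 0.59 in CT26 (adjusted p = 0.105) and 0.44 in Pan02 (adjusted p = 0.119). Clk4 fell in B16 by 0.35 (adjusted p = 0.0294) and its value was 0.38 in CT26, and the F-test for Clk4, which overlaps Gm25082, gave an adjusted p of 0.0506. Neither B16 call held with the main axis as a covariate, where Clk1 stood at -0.21 (SE 0.13, against 0.12 before, adjusted p = 0.774) and Clk4 at -0.28 (SE 0.11, against 0.06 before, adjusted p = 0.639): the differences shrank and the spread grew. In CT26 the same covariate brought Clk1 past the threshold, at 0.33 (SE 0.05, against 0.15 before, adjusted p = 0.0432), with a smaller difference and a smaller spread, and Clk4 stood at 0.25 (adjusted p = 0.0990).

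Among splicing and decay factors, single members moved while no list was called on average. Of all 8775 tested genes 2261 were called, so called members alone do not set a list apart. Of 12 SR proteins, 4 rose and 2 fell (camera adjusted p = 0.158), with Srsf6 and Srsf4 (0.08) higher and Tra2b (-0.10) and Srsf7 (-0.04) lower. Of 10 CLK, SRPK and DYRK kinases, 2 fell (adjusted p = 0.444), both SR protein kinases: Srpk2 fell by 0.31 (adjusted p = 3.69e-08) and Srpk1 by 0.12. Of 23 hnRNP proteins, 3 rose and 2 fell (adjusted p = 0.911), among them Hnrnpc (0.07), Hnrnpll (0.09), Hnrnpul1 (-0.07) and Hnrnpr (-0.11). Of 42 core spliceosome genes, 4 rose and 7 fell (adjusted p = 0.963). There the subunits of the U2AF factor, which recognises the 3′ splice site, moved apart: U2af1 rose by 0.10 and U2af2 fell by 0.12, while Prpf31 fell by 0.13 and Snrpa1 by 0.16. Of 15 nonsense-mediated decay factors, 1 rose, Upf3a (0.07), with an adjusted p of 0.719 for the list. In these lists the counts were the same adjusted over the list alone. The hnRNP and core spliceosome lists had means just below 0 (-0.006 and -0.002) and a test direction above it.

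The 3 lists called on average concerned stress and sterol genes, with small shifts. Of 17 ATF4 integrated stress response genes, 6 rose and 1 fell (adjusted p = 0.0183), among them the pseudokinase Trib3 (0.18, adjusted p = 1.77e-07), Chac1 (0.12), Atf4 (0.06) and Asns (0.06). Of 15 NRF2 targets, 6 rose and 1 fell (adjusted p = 0.0183), among them the glutathione synthesis enzyme Gclc (0.14), the autophagy receptor Sqstm1 (0.13, adjusted p = 4.01e-09), Abcc1 (0.13) and Txnrd1 (0.07). Of 23 genes of cholesterol synthesis and uptake, 8 fell (adjusted p = 0.0200), among them the mevalonate pathway enzymes Pmvk (-0.24, adjusted p = 1.34e-09), Mvd (-0.17) and Fdps (-0.08), and Dhcr7 (-0.11). The counts were the same adjusted over the list alone. None of these calls held with an estimated correlation: the adjusted p = 0.469 with an estimated correlation for ATF4 and the adjusted p = 0.314 with an estimated correlation for each of NRF2 and cholesterol. As many lists were called in 66 of 100 relabellings of the libraries within lines, the real labels included, so chance cannot be excluded for their number, and the ATF4 adjusted p was 0.0653 at a filter of 5 TPM.

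The other lists were not called on average. Of 18 unfolded protein response genes, 3 rose and 1 fell, or 2 and 1 adjusted over the list alone (adjusted p = 0.175), with Edem1 at 0.10, Dnajb9 at 0.09, Hyou1 at 0.05 and Pdia4 at -0.04. Of 13 heat shock genes, 2 fell (0.911), the co-chaperones Dnajb1 (-0.06) and Stip1 (-0.04), with a list mean of -0.002 against a test direction above 0. Of 7 NF-kB targets, 3 fell (0.175): Nfkbie (-0.11), Nfkb2 (-0.06) and Csf1 (-0.06). Of 7 interferon-stimulated genes, 1 fell, Bst2 (-0.06), and the list had an adjusted p of 0.719. Neither the 12 p53 targets (0.719) nor the 9 genes of MHC class I antigen presentation (0.963) had a called member, with Cdkn1a at 0.02, Mdm2 at 0.07 and B2m at -0.01. Of 7 immediate early genes, 2 rose (0.220), the phosphatases Dusp6 (0.07) and Dusp4 (0.05). Of 19 hypoxia and glycolysis genes, 6 fell (0.147), among them Bnip3 (-0.15), Pdk1 (-0.13), P4ha1 (-0.12) and Ndrg1 (-0.11). Apart from the unfolded protein response, each count so far was the same adjusted over the list alone. Only 2 aryl hydrocarbon receptor targets were tested in every line, and neither was called.

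Proliferation and biosynthesis genes went both ways. Of 25 G1/S genes, 3 rose and 3 fell, or 4 and 3 adjusted over the list alone (adjusted p = 0.730), with Tyms (0.09) and Mcm3 (0.04) higher and Uhrf1 (-0.09) and Ccne1 (-0.06) lower. Of 25 G2/M genes, 5 rose and 5 fell (0.669), with Nusap1 (0.14) higher and Plk1 (-0.09), Birc5 (-0.09) and Bub1 (-0.20) lower. Of 24 ribosome biogenesis genes, 2 rose and 3 fell (0.911): Gnl3 (0.12) and Utp20 (0.09) were higher and Dkc1 (-0.09) and Polr1b (-0.06) lower. Of 28 nuclear-encoded oxidative phosphorylation genes, 1 rose and 3 fell (0.669). Ndufs3 led these, with a fall of 0.30 (SE 0.012) from 121 to 97.6 TPM and an adjusted p of 2.44e-19, ahead of Ndufa9 (-0.08) and Ndufs1 (-0.04), while Ndufb5 rose by 0.06. The G2/M, biogenesis and oxidative phosphorylation counts were the same adjusted over the list alone. Of 44 cytosolic ribosomal proteins, 2 rose, Rps20 (0.04) and Rpl4 (0.02), and 0 adjusted over the list alone (0.719), with a mean of -0.002 against a test direction above 0. Of 13 mitochondrially encoded mRNAs, mt-Nd3 (0.18) and mt-Nd1 (0.10) rose, and 0 adjusted over the list alone (0.0530). That list was called with the main axis as a covariate (0.0369) and when 1 of 15 libraries was left out (0.0177 at the lowest), and its adjusted p was 0.236 after quantile normalization and 0.840 with an estimated correlation. The share of mitochondrially encoded transcripts was higher with RECTAS in 6 of 7 lines, from 5.01 ± 0.216% to 5.57 ± 0.178% in CT26 and from 6.00 ± 0.174% to 6.53 ± 0.265% in WEHI3 (exact p = 0.1 in both, the smallest possible), and in the other lines the exact p was 0.3 to 0.7.

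**Figure D3:**
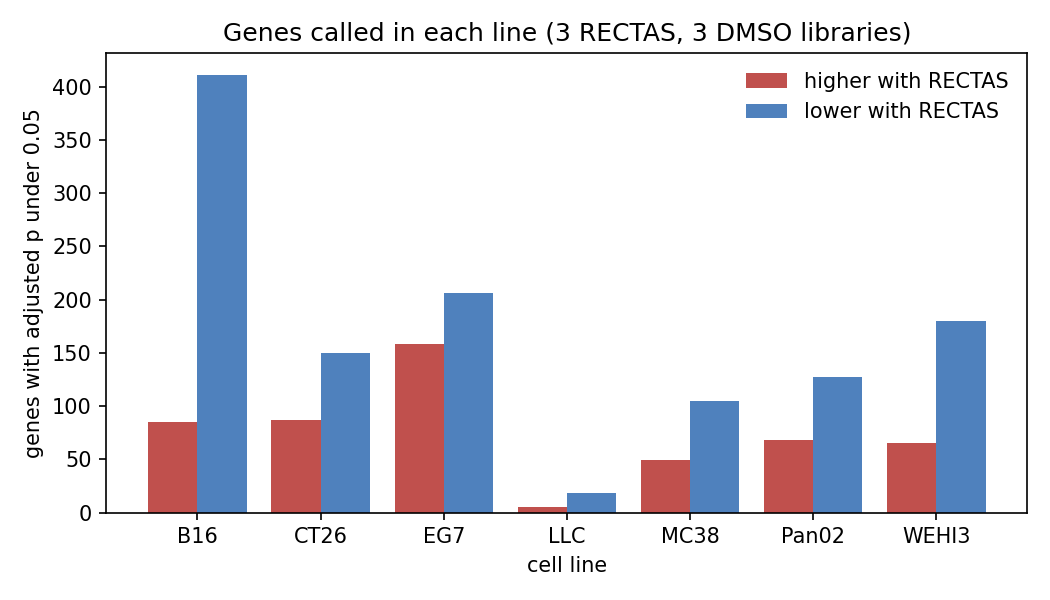
Number of genes with an adjusted p under 0.05 in each line, higher (red) or lower (blue) with RECTAS, from a limma fit of the 6 libraries of the line. B16 had 85 higher and 411 lower, and LLC had 5 and 18.

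In B16, 85 genes were called higher and 411 lower of 12097 tested. H2bc4 rose from 3.73 ± 0.666 to 8.62 ± 0.707 TPM (log2 difference 1.03, SE 0.12, adjusted p = 0.0133), and Luc7l rose from 48.3 ± 1.67 to 75.6 ± 4.36 TPM (0.64, adjusted p = 0.00398). Evi5 (chromosome 5, 107744795 to 107875107, opposite Gm43592), a regulator of Rab GTPases, fell by 1.13, from 12.98 ± 0.713 to 5.43 ± 0.738 TPM. Cwc27, Slc25a40 and the pseudogene Cyp4f41-ps fell by 1.12, 1.04 and 1.16. The 7SL RNA copies Rn7s1 and Rn7s2 had identical values (0.71) and cannot be separated. Among the lists, 11 CLK, SRPK and DYRK kinases had 3 falls, or 4 adjusted over the list alone, with a mean of -0.271 (adjusted p = 0.0179; adjusted p = 0.462 with an estimated correlation): Srpk2 fell by 0.85, from 29.3 ± 1.67 to 15.9 ± 2.30 TPM, beside Clk1 and Clk4, and Prpf4b stood at -0.47. Of 18 ATF4 genes, 3 rose and 1 fell, or 10 and 3 adjusted over the list alone (adjusted p = 2.16e-06; adjusted p = 0.0613 with an estimated correlation), with Trib3 (0.42), Asns (0.23) and Atf4 (0.18) higher and Aldh1l2 (-0.29) lower. Of 24 cholesterol genes, 5 fell, or 7 adjusted over the list alone (adjusted p = 0.00617; adjusted p = 0.286 with an estimated correlation), including Hmgcs1 (-0.32), Idi1 (-0.40) and Mvd (-0.28). The 3 DMSO libraries of B16 scored -1.11 to -1.01 and its RECTAS libraries -0.06, 2.19 and 1.02 on the main axis of variation between replicates, and with that axis as a covariate 2 genes were called in place of 496. The count lay between 26 and 1455 without 1 library at a time, with every library moving it by over 1.5 times, and falls were 82.9% of the calls as deposited, 58.6% after median-ratio scaling and 59.4% after quantile normalization, while with the GC and length trend removed rises were in the majority (536 higher, 344 lower, 39.1% falls).

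In CT26, 87 genes were called higher and 150 lower of 11938. H2bc4 rose from 5.42 ± 0.447 to 13.5 ± 1.43 TPM (1.17, adjusted p = 0.00307), and the histone H2B genes H2bc21 (0.87) and H2bc12 (0.72) and the chemokine gene Ccl25 (0.83) followed. Hacd1 (chromosome 2, 13850282 to 14056135), a dehydratase of very-long-chain fatty acid elongation, fell by 0.82, from 130.2 ± 3.005 to 73.3 ± 4.13 TPM (adjusted p = 0.00159). Cwf19l1, Rsph3a and Cmc4 fell by 0.83, 0.83 and 0.80. Of 23 ATF4 genes, 1 rose, or 3 adjusted over the list alone, the stress protein gene Nupr1, from 99.2 ± 5.36 to 148 ± 7.79 TPM (list adjusted p = 0.00648; adjusted p = 0.450 with an estimated correlation). The lists of SR proteins (0.0250) and mitochondrially encoded mRNAs (0.00792) were called higher, and those of cytosolic ribosomal proteins (0.000161), oxidative phosphorylation (0.00792) and cholesterol (0.0179) lower, each with an adjusted p = 0.688 with an estimated correlation. The calls of the mitochondrially encoded mRNAs, cytosolic ribosomal proteins and oxidative phosphorylation run with the main axis, where they lay at percentiles 14.4, 96.0 and 86.4 and the CT26 libraries scored -2.06, 0.75 and -0.63 with RECTAS and -0.08, 0.21 and 1.81 with DMSO, so they cannot be set apart from it. The count lay between 27 and 250 without 1 library at a time, with every library but RECTAS replicate 2 moving it by over 1.5 times.

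In EG7, 158 genes were called higher and 206 lower of 11112. Scn4b (chromosome 9, 45138395 to 45154152), a sodium channel beta subunit, rose from 3.34 ± 0.154 to 9.36 ± 0.245 TPM (1.26, adjusted p = 0.000253). Nacc2 rose by 0.995, H2bc4 by 0.97, from 0.877 ± 0.146 to 2.70 ± 0.414 TPM, and the second ID of Zc3h11a by 0.98. Trav13n-4, a variable segment of the T-cell receptor alpha locus (chromosome 14, 53362267 to 53364106), fell by 1.26, from 52.7 ± 1.94 to 21.4 ± 1.28 TPM (adjusted p = 0.00019), and is uncertain because related segments can share reads. Tmem250-ps, Rsph3b and Xkr5 fell by 0.97, 0.85 and 0.82. The hypoxia list was called lower (22 genes, 1 fell, Bnip3 at -0.39, adjusted p = 0.0133) and ribosome biogenesis higher (24 genes, 2 rose, Gnl3 at 0.17 and Utp20 at 0.21, adjusted p = 0.0271), with the same counts adjusted over the list alone and an adjusted p = 0.869 with an estimated correlation for both. The 9 T lymphoid markers had no called member (0.930). Without 1 library at a time the count lay between 114 and 304, with every library but RECTAS replicate 1 moving it by over 1.5 times.

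LLC had the fewest calls, 5 higher and 18 lower of 11848. H2bc4 rose from 27.1 ± 0.555 to 76.0 ± 4.57 TPM (1.45, adjusted p = 0.000709), H2bc12 from 3.36 ± 0.487 to 9.77 ± 1.85 TPM (1.297), Sdhaf4 by 0.59 and Nprl3 by 0.52. Xkr5 fell by 0.80, from 10.3 ± 0.504 to 5.47 ± 0.146 TPM, and Dus4l, a tRNA dihydrouridine synthase (chromosome 12, 31640050 to 31654826), fell by 0.78, followed by Rsph3a and Cwf19l1 at 0.72 each. The ATF4 (0.0407), unfolded protein response (0.00380) and NRF2 (0.0228) lists were called higher with no called member, 0 also adjusted over the list alone, and each had an adjusted p = 0.463 with an estimated correlation. LLC DMSO replicate 2 stood at 2.72 on the main axis, and with that axis as a covariate 188 genes were called. Without 1 library at a time the count lay between 1 and 17, with every library but DMSO replicate 2 moving it by over 1.5 times, and falls were 78.3% of the calls as deposited and 58.3% after quantile normalization.

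In MC38, 49 genes were called higher and 105 lower of 11959. H2bc4 rose from 6.01 ± 0.628 to 16.3 ± 1.99 TPM (1.301, adjusted p = 0.00777). Ccdc122, opposite Lacc1 and so uncertain, rose by 1.28, with Ccl25 at 0.70 and Nprl3 at 0.60. Slc5a4a (chromosome 10, 76147451 to 76189265), of the sodium-glucose transporter family, fell by 0.94, from 13.5 ± 0.381 to 6.59 ± 0.241 TPM (adjusted p = 0.00477), and Hacd1 fell by 0.82, from 20.2 ± 1.09 to 11.02 ± 1.02 TPM. Larger falls were uncertain: Pcdhgc4, from 6.78 ± 3.63 to 0.650 ± 0.455 TPM, shares exons with the protocadherin gamma cluster, and a second ID of Fam220a (-1.46) overlaps the first. The heat shock list was called higher with 0 called members (14 genes, 0 also adjusted over the list alone, Hspa4l at 0.19 and Hsph1 at 0.09, adjusted p = 0.0109; adjusted p = 0.959 with an estimated correlation). Leaving out 1 library at a time gave 34 to 80 genes, with every library moving the count by over 1.5 times.

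In Pan02, 68 genes were called higher and 127 lower of 11589, and the cholesterol list was the only list in a single line called also with an estimated correlation. Of 25 cholesterol genes, 5 fell, or 18 adjusted over the list alone, with a mean of -0.196 (adjusted p = 2.97e-13; adjusted p = 0.0251 with an estimated correlation). Pmvk fell from 49.4 ± 0.806 to 35.4 ± 2.12 TPM (adjusted p = 0.00718), and Mvd, Tm7sf2 and Cyp51 fell by 0.42, 0.32 and 0.26. Of 21 hypoxia and glycolysis genes, 4 fell, or 14 adjusted over the list alone (adjusted p = 8.39e-10; adjusted p = 0.203 with an estimated correlation): Pdk1, a kinase that inhibits pyruvate dehydrogenase, by 0.38, Bnip3 by 0.42, P4ha1 by 0.26 and Ndrg1 by 0.24. Of 6 epithelial markers, 2 fell, or 5 adjusted over the list alone (adjusted p = 3.72e-05; adjusted p = 0.203 with an estimated correlation), Krt8 from 1425 ± 34.5 to 1233 ± 20.3 TPM and Krt7 by 0.19, with Krt19 at -0.21 and Krt18 at -0.14. Of 6 aryl hydrocarbon receptor targets, 1 rose, or 3 adjusted over the list alone (adjusted p = 0.000454; adjusted p = 0.203 with an estimated correlation), Aldh3a1, from 118 ± 0.581 to 149 ± 2.75 TPM. H2bc4 rose from 99.2 ± 5.31 to 219.7 ± 3.32 TPM (1.14, adjusted p = 0.000128), with Ccl25 at 1.04, Ccdc122 at 0.91 and Nprl3 at 0.65. The largest falls that the naming rule allowed were Rsph3b (-0.90), Cwf19l1 (-0.84), Alkbh3 (-0.81) and Wdr78 (-0.75, opposite Mier1).

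The other lists called in Pan02 were smaller shifts. NRF2 targets were higher, with Hmox1 (0.31) and Sqstm1 (0.20) called, or 3 adjusted over the list alone (adjusted p = 0.00265; adjusted p = 0.381 with an estimated correlation). Immediate early genes were higher, with Ier3 (0.34) called, or 4 adjusted over the list alone (adjusted p = 0.00215; adjusted p = 0.467 with an estimated correlation). The unfolded protein response was lower, with the chaperone Hspa5 (-0.18) called, or 3 adjusted over the list alone (adjusted p = 0.00452; adjusted p = 0.203 with an estimated correlation). The G2/M (0.00319), mitochondrial mRNA (0.00579), SR protein (0.0203), p53 (0.0216) and hnRNP (0.0418) lists were called higher and NF-kB targets (0.0318) lower, with adjusted p = 0.365 to 0.492 with an estimated correlation. Leaving out 1 library of Pan02 at a time gave 46 to 69 genes, with every library moving the count by over 1.5 times, and falls were 65.1% of the calls as deposited and 53.7% after median-ratio scaling.

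In WEHI3, 65 genes were called higher and 180 lower of 11789. Ppid (chromosome 3, 79591342 to 79603650), the cyclophilin that binds Hsp90, rose from 67.9 ± 2.23 to 120.3 ± 4.41 TPM (0.82, adjusted p = 0.000293), with Ccdc122 at 0.83, Ccl25 at 0.78 and the carbonic anhydrase gene Car7 at 0.65. Mtrex, the RNA helicase that feeds the nuclear exosome, fell by 0.80, from 40.4 ± 0.145 to 22.8 ± 2.52 TPM (adjusted p = 0.00596), with Plpp1 on the other strand, and Xkr5, Slc4a7 and Stxbp3 fell by 0.91, 0.89 and 0.83. Of 13 mitochondrially encoded mRNAs, 3 rose, or 6 adjusted over the list alone (adjusted p = 9.64e-07; adjusted p = 0.563 with an estimated correlation): mt-Cytb (0.14), mt-Nd2 (0.22) and mt-Co1 (0.10), beside the higher mitochondrial share of this line. SR proteins (0.0388) were called higher, with Srsf6, and cholesterol genes (0.0498) lower, with Pmvk (-0.28), each with 1 called member and an adjusted p = 0.563 with an estimated correlation, and cytosolic ribosomal proteins (0.0388) had a mean of only 0.008 and an adjusted p = 0.690 with an estimated correlation. Neither the 11 myelomonocytic markers (0.174) nor the 5 T lymphoid markers (0.194) had a called member. With the main axis as a covariate 160 genes were called, and without 1 library at a time the count lay between 62 and 98, with every library moving it by over 1.5 times. Falls were 73.5% of the calls as deposited and 62.6% after median-ratio scaling.

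Further lists were called in B16. NRF2 targets (2.16e-06, 2 rose, or 3 adjusted over the list alone, Sqstm1 at 0.21 and Osgin1 at 0.29), the unfolded protein response (3.70e-06, 1 rose, or 4, Herpud1 at 0.25), ribosome biogenesis (0.00237, 1 rose, Nop16 at 0.17), cytosolic ribosomal proteins (3.12e-12, 0 called) and oxidative phosphorylation (0.00923, 1 fell, Ndufs3 at -0.28) were called higher, and hnRNP proteins (0.00652, 1 fell, or 1 rose and 10 fell adjusted over the list alone, Hnrnpr at -0.28) lower. In the other 3 of these lists the counts were the same adjusted over the list alone. Their adjusted p = 0.0613 to 0.617 with an estimated correlation, and the mean of the oxidative phosphorylation list turned from 0.010 to -0.010 under quantile normalization. Scaling moved the mean of every list called in B16 except the kinases by over 1.5 times: under median-ratio scaling cholesterol went from -0.138 to -0.071, hnRNP proteins from -0.183 to -0.114, ATF4 from 0.071 to 0.138, the unfolded protein response from 0.069 to 0.137, NRF2 from 0.075 to 0.143, cytosolic ribosomal proteins from 0.072 to 0.141 and ribosome biogenesis from 0.013 to 0.081. Such moves also held for 3 lists called in CT26, 2 in LLC and 2 in WEHI3. Several lists called in B16 lay toward the end of the main axis that fits their direction, with the B16 RECTAS libraries above its DMSO libraries on that axis. The median percentile of the loading was 96.0 for cytosolic ribosomal proteins, 86.4 for oxidative phosphorylation, 82.1 for NRF2, 75.0 for ATF4, 18.6 for hnRNP proteins and 15.7 for the CLK, SRPK and DYRK kinases, so these calls cannot be set apart from the axis. The unfolded protein response (50.5), ribosome biogenesis (54.4) and cholesterol (47.2) lay near its middle. Melanocyte markers in B16 (8 genes, 0.599) had no called member, or 1 fall adjusted over the list alone. Mesenchymal markers in B16, CT26, LLC, MC38 and Pan02 (0.0969 to 0.938) had no called member. In all, every gene called in a single line had its RECTAS libraries all above or all below its DMSO libraries, and such separation held for 13.2% (LLC) to 34.9% (B16) of all tested genes where chance gives 10%.

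The effect of RECTAS differed between lines for 269 genes, 145 of them also called on average. The number of genes whose RECTAS effect differs between lines was 515 with no filter, 654 with the GC and length trend removed, and 77, 130, 170, 1112 or 176 without the line B16, CT26, EG7, LLC or MC38. Pak1ip1, a nucleolar protein, stood at -0.60 in EG7, and the next largest difference was -0.17 in B16 (F-test adjusted p = 6.05e-12). Tmem250-ps stood at -0.97 in EG7 and -0.25 in LLC (2.55e-10), and Hacd1 stood at -0.82 in CT26 and MC38 and -0.17 in EG7 (2.30e-08). Mtrex stood at -0.80 in WEHI3, -0.77 in CT26 and -0.03 in EG7 (5.71e-06). Pop4, a subunit of RNase P and RNase MRP, stood at -0.66 in WEHI3 and near 0 in B16 (3.89e-05). H2bc21 stood at 0.92 in EG7 and 0.30 in Pan02 (1.22e-05). Kctd2 stood at -0.11 in B16 and at 0.31 to 0.47 in the other lines (1.43e-05), and Fam136a at 0.13 in B16 and -0.23 in CT26 (2.14e-05). Vps41, a subunit of the HOPS tethering complex, stood at -0.46 in EG7 and Pan02 and 0.03 in CT26 (3.41e-05), and Rasa3 at -0.60 in MC38 and -0.18 in CT26 (0.000123). Without LLC DMSO replicate 2 the number of genes was 876, and with B16 DMSO replicate 2 or B16 RECTAS replicate 2 left out it was 159 or 168.

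List scores differed between lines for 7 lists, and for 12 after median-ratio scaling. Cholesterol synthesis and uptake stood at -0.20 in Pan02, -0.14 in B16 and 0.06 in EG7 (adjusted p = 6.78e-07), and hypoxia and glycolysis at -0.18 in Pan02 and -0.09 in EG7 (0.00182). The ATF4 list stood at 0.13 in CT26, 0.09 in B16 and -0.04 in Pan02 (0.00182), and the unfolded protein response at 0.07 in B16 and -0.06 in Pan02 (0.0250). CLK, SRPK and DYRK kinases stood at -0.29 in B16 and 0.13 in CT26 (0.0453), a contrast that runs with the main axis, where this list lay at percentile 15.7, the B16 RECTAS libraries lay above its DMSO libraries and CT26 RECTAS replicate 1 stood at -2.06. NRF2 targets (0.0250) and immediate early genes (0.0275) differed as well, the latter with 0.13 in Pan02. Without 1 library at a time the number of lists lay between 3 (without Pan02 RECTAS replicate 2) and 12 (without CT26 RECTAS replicate 2 or LLC DMSO replicate 2), with 4 without WEHI3 DMSO replicate 1 and 11 without B16 RECTAS replicate 1.

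**Figure D4:**
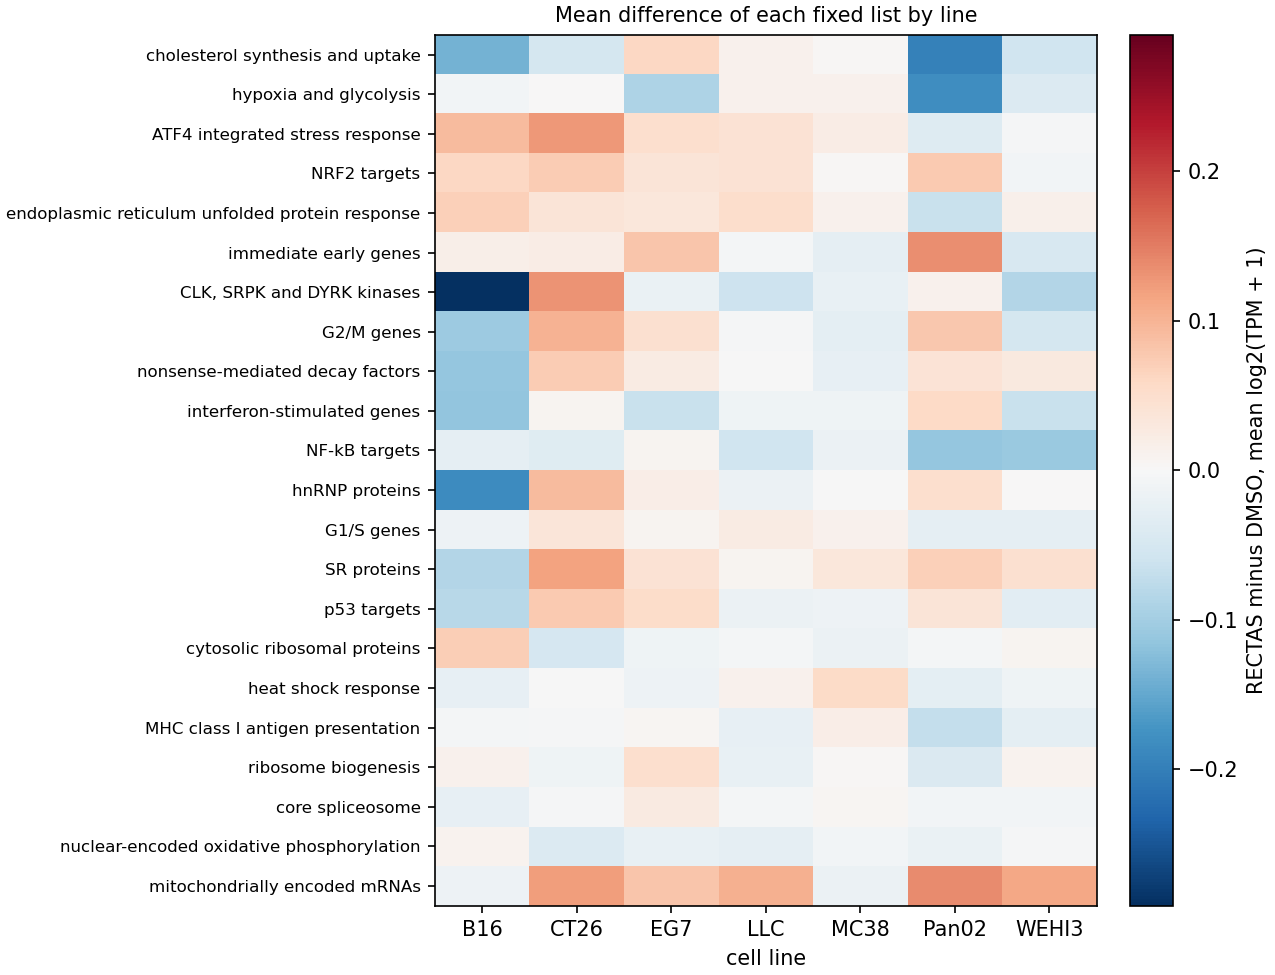
Difference, RECTAS minus DMSO, of the mean log2(TPM + 1) of the tested members of 22 lists in each of the 7 lines, with lists ordered by the p of the F-test between lines. Cholesterol genes stood at -0.20 in Pan02, and the kinase list at -0.29 in B16 and 0.13 in CT26.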

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

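The removal of the GC and length trend was chosen after the result was seen, and so was the fit with the main axis as a covariate; the other tests of this part were chosen before. The effect of RECTAS differed between the 7 lines for 269 genes by the limma F-test. Among the genes with the largest shared changes, the adjusted p of that test was 0.00249 for H2bc4 (0.56 in WEHI3 to 1.45 in LLC), 0.000177 for Nprl3 (0.10 in B16 to 0.71 in EG7), 1.22e-05 for H2bc21 (0.30 in Pan02 to 0.92 in EG7), 0.00425 for Luc7l (0.31 in CT26 to 0.64 in B16), 0.0377 for Xkr5 (-0.91 in WEHI3 to -0.49 in MC38), 0.000137 for Rsph3b (-0.90 in Pan02 to -0.19 in B16) and 0.023 for Slc25a40 (-1.04 in B16 to -0.23 in WEHI3). These genes kept 1 sign in all 7 lines and differed in size. It was 0.029 for Clk1 (-0.63 in B16, 0.59 in CT26) and 0.00545 for Srsf6 (0.06 in Pan02 to 0.26 in WEHI3). The 10 smallest values also took in Pak1ip1 (6.05e-12), Tmem250-ps (2.55e-10), Hacd1 (2.3e-08), Mtrex (5.71e-06), Kctd2 (1.43e-05), Fam136a (2.14e-05), Vps41 (3.41e-05), Pop4 (3.89e-05) and Rasa3 (0.000123).

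Scores differed between the lines for 7 lists. The adjusted p was 6.78e-07 for cholesterol synthesis and uptake, 0.00182 for the ATF4 integrated stress response and for hypoxia and glycolysis, 0.025 for the endoplasmic reticulum unfolded protein response and for NRF2 targets, 0.0275 for immediate early genes and 0.0453 for CLK, SRPK and DYRK kinases.

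The differences in B16 ran against those in CT26 across genes (r = -0.113), while the other 20 pairs of lines were above 0. With the GC and length trend removed r was -0.0392 (-0.128 to 0.0593 without 1 library at a time), and with the first axis of variation between replicates projected out it was 0.106 (0.0682 to 0.121). Leaving out CT26 RECTAS replicate 1 brought r to 0.00585, the highest value without 1 library, and the lowest was -0.221. None of these tests passed the bound set for it beyond the spread of the left-out libraries, so all 3 explanations stay open, and so does a difference between the cell lines, which was not tested. In B16 the DMSO libraries lay at 1 end of that axis, so the axis and the treatment are partly confounded there. The gene loadings of the axis had a correlation of 0.476 with GC content and -0.382 with log10 exonic length, so these explanations overlap.

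More genes were called lower than higher on average (61.7% lower). Falls were 51.0% of the calls under median-ratio scaling and 45.6% with the GC and length trend removed. The excess among the calls on average thus depended on how the libraries were scaled. Removing the trend also centres the libraries of a line on a common mean. Its effect therefore cannot be credited to GC content and length apart from scaling. Among genes called in at least 3 lines the excess stayed, with 75.0% falls as deposited and 69.1% under median-ratio scaling. With median-ratio scaling and with the trend removed, rises on average grew (865 to 1118 and 1517) and falls dropped (1396 to 1165 and 1270). Both shares met the bounds set for scaling and for GC content and length. Neither is shown to be the cause, and both stay open. Among called genes, 17 of 49 with 1 annotated exon fell, against 1378 of 2211 with several exons, an odds ratio of 3.11 (95% interval 1.67 to 6.02, Fisher's exact p = 0.000145). A splicing-related loss would give such a difference, whether real or from reads on junctions the annotation lacks. The interval and the p treat genes as independent, which they are not. Genes with 1 exon were also not matched to the others on GC content, length or expression. The test therefore cannot decide on a splicing-related loss, and the explanations of the excess are not exclusive.

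H2bc4 and H2bc21 rose in all 7 lines. A larger share of cells in S phase would raise the other cluster histone genes too. The median difference of 47 such genes was 0.0262 (SD 0.115), with 0.41 for H2bc12 as the highest. Many of them had low TPM, as H3c7 at 0.52 on average, where log2(TPM + 1) understates a rise. The most abundant, H4c9 (29.1 TPM) and H1f2 (16.8 TPM), stood at 0.13 and 0.15. Whether libraries of polyadenylated RNA would show such a rise is unknown, so the histone genes cannot decide on S phase. A larger share of cells in S phase would raise the G1/S genes as well. The 25 G1/S genes had a mean difference of 0.0018, with 3 rises and 3 falls. Their scores lay between -0.026 (Pan02) and 0.034 (CT26). These values argue against a larger S phase share as the main source of the H2bc4 and H2bc21 rises. Reads moved between near-identical copies would leave the sum of H2bc genes as it was, but the summed TPM of 14 H2bc genes was higher in 7 of 7 lines, with a mean log2 ratio of 0.694 (SD 0.312, 0.316 to 1.13). That sum includes H2bc4, so it argues against reads moved from other H2bc genes as the source of the H2bc4 rise only. It cannot tell whether H2bc21 rose through reads shared with H2bc4. A shift of these transcripts toward polyadenylated forms, which the library kit captures, may contribute and was not tested.

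Chance was also examined by relabelling libraries. Within 1 line the 6 libraries make 10 splits, too few for a share under 0.05, and the real split gave the most calls in 1 of 10 each time: 496 in B16 (highest other 3), 237 in CT26 (2), 364 in EG7 (2), 23 in LLC (8), 154 in MC38 (2), 195 in Pan02 (4) and 245 in WEHI3 (5). Of 100 relabellings within lines, the real labels included, 1 gave as many genes called on average (2261, highest other 224). For genes shared by at least 3 lines, 1 also gave as many (128, highest other 52), so chance can be excluded for both counts. For lists called in single lines 1 gave as many (38, highest other 36), a narrow margin. That count lay between 34 and 42 without 1 library at a time and was 1 with an estimated correlation, so chance stays open for it. For the genes that differ between lines, 4 gave as many (269, highest other 1410), and for list scores 4 gave as many (7, highest other 17). Both shares lay under 0.05, but other labellings exceeded both counts. Relabelling also removes the RECTAS effect that the lines share, so it cannot decide whether the effects differ between lines. Chance stays open for both counts. The cause of the count of 1410 was not tested. For the lists called on average (3), 66 gave as many (highest other 9), so chance cannot be excluded.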

How the results depend on the processing

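The main axis covariate and the removal of the GC and length trend were chosen after the result was seen; all other alternatives were chosen before. No called difference of a named gene and no called list on average turned its direction, but other values did. The share of falls among the calls on average (61.7%) became 47.1% under quantile normalization and 45.6% with the GC and length trend removed, and that of B16 (82.9%) became 39.1% with the trend removed. The mean of the B16 oxidative phosphorylation list went from 0.010 to -0.010 under quantile normalization, and r between B16 and CT26 from -0.113 to 0.106 with the main axis projected out. Of the values of genes named on average, 595 of 599 under other settings and 1207 of 1218 without 1 library kept their direction and side of the threshold, and 176 of 178 and 420 of 420 did for genes named between lines. For genes named in single lines these were 638 of 716 and 226 of 335, with the rest losing their call, and for lists on average 163 of 173 (6 gained and 4 lost a call) and 909 of 924 (15 gained). The similarity of the lines stayed between 0.159 (pseudocount 0.1) and 0.302 (filter of 5 TPM). The depth is unknown, so no limit from counting could be set; for the shifts below, except where the setting itself asks for more or tests fewer or more genes, the cause was not tested.

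With no filter, genes called were 98 in B16, 81 in CT26, 166 in EG7, 12 in LLC, 48 in MC38, 50 in Pan02 and 113 in WEHI3, with 515 genes whose RECTAS effect differs between lines and 39 in at least 3 lines. Without the intensity trend they were 318 in B16, 79 in CT26, 4 in LLC, 58 in MC38, 95 in Pan02 and 142 in WEHI3, with 67 in at least 3 lines. A log2 difference of at least 0.58, a stricter demand, left 101 in B16, 37 in CT26, 49 in EG7, 14 in LLC, 26 in MC38, 25 in Pan02, 41 in WEHI3, 15 on average and 22 in at least 3 lines. A spread shared by all 42 libraries gave 2387 in B16, 1048 in CT26, 817 in EG7, 519 in LLC, 446 in MC38, 833 in Pan02 and 669 in WEHI3, and the 7 lines as units gave 1015 on average. Quantile normalization gave 12 in LLC, leaving out mitochondrial genes gave 5 in LLC, and median-ratio scaling gave 12 list scores that differ. The main axis covariate gave 2 in B16, 188 in LLC and 160 in WEHI3. Removing the GC and length trend gave 880 in B16, 518 in CT26, 551 in EG7, 63 in LLC, 335 in Pan02 and 654 between lines. An estimated correlation left 0 lists on average and 1 in single lines (cholesterol in Pan02), and fry, which does not compare a list with other genes, called 7 and 17. Between lines, leaving out B16, CT26, EG7, LLC or MC38 gave 77, 130, 170, 1112 or 176 genes.

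Replicate number as a block gave 26 in B16, 29 in CT26, 150 in EG7, 2 in LLC, 4 in MC38, 46 in Pan02, 52 in WEHI3 and 20 in at least 3 lines, and on average called Clk2 and the list of mitochondrially encoded mRNAs. The numbers do not pair the libraries: of 21 correlations between same-numbered DMSO and RECTAS libraries, 2 were over 0.1 (-0.122 to 0.286), and 7 of 21 DMSO libraries matched their own number best.

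Without 1 library at a time, B16 gave 26 to 1455 genes (51, 26 and 80 without DMSO replicates 1, 2 and 3, and 1455, 103 and 33 without RECTAS replicates 1, 2 and 3). CT26 gave 27 to 250 (33, 27 and 60 without DMSO replicates 1, 2 and 3, 66 and 30 without RECTAS replicates 1 and 3). EG7 gave 114 to 304 (136, 130 and 114 without DMSO replicates 1, 2 and 3, 237 and 177 without RECTAS replicates 2 and 3). LLC gave 1 to 17 (1 and 1 without DMSO replicates 1 and 3, 1, 2 and 1 without RECTAS replicates 1, 2 and 3), MC38 34 to 80 (80, 51 and 34 without DMSO replicates 1, 2 and 3, 41, 35 and 39 without RECTAS replicates 1, 2 and 3), Pan02 46 to 69 (52, 46 and 67 without DMSO replicates 1, 2 and 3, 46, 69 and 65 without RECTAS replicates 1, 2 and 3) and WEHI3 62 to 98 (79, 62 and 83 without DMSO replicates 1, 2 and 3, 91, 98 and 65 without RECTAS replicates 1, 2 and 3). On average over the lines 2149 to 2384 genes were called, and 159 to 876 differed between lines (159 without B16 DMSO replicate 2, 168 without B16 RECTAS replicate 2 and 876 without LLC DMSO replicate 2). The mitochondrially encoded mRNAs were called on average without B16 DMSO replicate 3 or RECTAS replicate 1, EG7 DMSO replicate 2 or RECTAS replicate 1, LLC DMSO replicate 3 or RECTAS replicates 1 or 2, MC38 DMSO replicate 3 or RECTAS replicate 1, Pan02 DMSO replicates 2 or 3 or RECTAS replicates 2 or 3, or WEHI3 RECTAS replicates 1 or 2. Lists called were 3 to 4 on average and 34 to 42 in single lines, and list scores that differ were 3 to 12 (3 without Pan02 RECTAS replicate 2, 4 without WEHI3 DMSO replicate 1, 11 without B16 RECTAS replicate 1, 12 without CT26 RECTAS replicate 2 or LLC DMSO replicate 2). Fewer libraries lower the power of a line's fit, and with 2 libraries in 1 group the spread rests on 5 libraries.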

Other observations

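The comparison of the median share of decay isoforms in genes matched on transcript number was chosen after the result was seen; the other tests here were chosen before. Several genes called in at least 5 lines fell outside the naming rule and were chosen after their values were seen. Ddx39b, a helicase of splicing and mRNA export, fell by 0.26 on average and was called lower in 6 lines. Rtcb, the ligase that joins tRNA and Xbp1 exons, fell by 0.27, Dus2, a tRNA dihydrouridine synthase, by 0.37 and Dimt1, an rRNA methyltransferase, by 0.48, each called lower in 6 lines. The RNA-binding protein gene Rbmx fell by 0.34 and was called lower in 5 lines. Called higher were Dis3 (0.32, 6 lines), a nuclease of the exosome, Sat1 (0.31, 6 lines), an enzyme of polyamine breakdown, and Thrap3 (0.30, 5 lines), a splicing and mRNA decay factor. Pot1a, a telomere-binding protein, fell by 0.54 and was called lower in 6 lines.

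If RECTAS moves transcripts into isoforms subject to nonsense-mediated decay, genes that fell may carry annotated decay isoforms more often. Of 1395 genes that fell, 36.6% had one, against a median of 33.4% in 10000 draws of uncalled genes matched on expression and exon number, at percentile 99.6. The number of annotated transcripts was argued against as the source, since in draws matched on it the median was 33.3% and the percentile 99.7. Genes that rose also carried decay isoforms more often (36.4% against 30.2%, percentile 100), so the excess is not specific to falls and the direction of the change is not explained by it.

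Another hypothesis, that splicing is where the response enters, predicted more exons in called genes. Called genes had a median of 10 exons, against 9 in uncalled genes matched on expression and exonic length, at percentile 100 of 10000 draws (means 11.67 and 11.02). Other properties tied to exon number were not excluded, since the draws matched only expression and exonic length, and no junction or transcript values were at hand to measure splicing.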
